A study of Arabidopsis thaliana with 30 samples.

How the data were processed

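Arabidopsis thaliana seedlings had grown for 5 days on medium with sucrose in long days, per the labels' protocols. The 30 libraries fell into 10 groups of 3, assigned from the sample titles. Whole root meristems gave the 18 libraries of the ZAT14-like and ZAT14 lines and the 6 of the pear sextuple mutant and Col-0. The other 6 came from protoplasts released from roots and sorted by fluorescence, whose low-input cDNA was amplified by PCR before library preparation, per the labels' protocols.

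The deposited values of the mutant and ZAT tables are FPKM, fragments scaled by gene length and library total, made by the authors with each library scaled on its own. TopHat2, HTSeq and the build TAIR10 are named in the submitters' processing notes, without versions, annotation or filters. The sorted-cell files hold deposited raw counts per gene in which reads had been aligned to TAIR10 and counted with featureCounts, and Bowtie2 is also named, per the submitters' processing notes. FPKM depends on the other genes of a library: where abundant genes hold a larger share, all others read lower. Counts from PCR-amplified cDNA without molecular identifiers are not independent molecules.

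Gene symbols, products and coordinates came from the TAIR10.1 annotation by locus code. It matched 31912 of 32678 genes in the mutant table, 32548 of 34218 in the ZAT table, where 1385 identifiers are not locus codes, and 32835 of 33602 in the sorted-cell files. Depth of the FPKM libraries was estimated from low values, which lie at multiples of what 1 read is worth given a gene's exon length. Within a tolerance of 0.05 reads, 34.0% to 36.7% of the low values looked at in the mutant table were whole, and 75.0% to 77.8% in the ZAT table, so these depths are estimates and the FPKM values were not turned back into counts.

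FPKM values were tested with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a trend) on log2(FPKM + 1), for genes with at least 1 FPKM in at least 3 libraries of the table. Fold changes are on that scale, which understates changes of low genes. The mutant table was fitted alone. The ZAT table was fitted as 6 group means over 18 libraries, with contrasts for each time against DMSO, the mean of both times against DMSO, 14 h against 10 h, the difference between the lines' responses, and the lines with DMSO alone. Counts were tested with edgeR 4.0.16 (TMM factors, filterByExpr, quasi-likelihood test); TMM factors ran from 0.717 to 1.01 in DMSO and 1.15 to 1.28 in estradiol libraries. All tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05.

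Gene lists numbered 21 with 310 distinct genes: PEAR family Dof factors, sieve element maturation, protophloem specification and CLE signalling, companion cell and phloem transport, xylem differentiation, procambium and HD-ZIP III, cytokinin response, auxin response, mitosis, DNA replication, cell cycle inhibitors and endocycle, PLETHORA and stem cell niche, ROP GTPases and RopGEFs, cell wall loosening, ribosome biogenesis, root hair and epidermis markers, root cap markers, endodermis and cortex markers, green tissue markers, wound, jasmonate and stress markers, and circadian clock. They were tested with camera at a preset correlation of 0.01 and adjusted over the lists of a comparison. With an estimated correlation no list call of any comparison held. Groups, tests, gene lists, the rule for named genes and the alternatives listed below were fixed before the data were examined. The list of ROP GTPases and RopGEFs was chosen knowing that these genes interested the study's authors, so it is not independent of the study.

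Named genes were the targeted genes, then the 10 largest rises and falls among called genes that have a symbol, a mean of at least 5 FPKM or CPM in the higher group and no overlap between groups, then up to 4 called members of each list by adjusted p. For the difference between the lines the 5 largest on each side were taken without the overlap condition. Other genes named in the text are list members, or are said to have been chosen after their values were seen; members outside the top 4 of a list were named where a count was small or as values that did not pass.

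The alternatives tried were a pseudocount of 0.1, no filter on low values, median-ratio rescaling of the libraries, an absolute log2 fold change of at least 1, leaving out each library, the replicate number as a block, fits of the compared groups only, DESeq2 1.42.0 and its size factors for the counts, and other list tests. A block across both lines, limma-voom with sample weights, and leaving out the 3 ZAT libraries numbered 2 were added after the data were seen.

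The steps were tested on simulated data with 200 changed genes in 10 draws per comparison. Changed genes were drawn only from those above a minimum of expected reads, and no shift of all genes was simulated. The recovered shares therefore do not cover low genes or a wide shift as in the mutant comparison. For the mutant comparison (17062 genes), 92.1% of 2-fold and 99.8% of 4-fold changes were recovered; for ZAT14-like induction (17157 genes) 95.8% and 99.6%, and for ZAT14 induction 96.3% and 100%. For PLT2 (24673 genes) with the spread estimated per gene, 0.1% of 2-fold and 17.2% of 4-fold changes were recovered. A first version of this simulation recovered no change at either size, and the settings with smaller spreads were added after that was seen: the spread of the abundance trend gave 4.5% and 49.5%, a spread of 0.1 gave 10.4% and 92.8%, and 0.05 gave 46.7% and 99.8%. Mean false calls were 12.6 for the mutant comparison, 10.2 and 8.6 for the ZAT14-like and ZAT14 inductions and 1.8 for PLT2 with the spread per gene. Of 10 simulated lists 1 was raised and was found, with 0 false lists among the others. The genes of these lists were drawn independently, so this does not test how camera behaves when genes are correlated.

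Between libraries of a group, log-scale values correlated across genes at 0.9896 to 0.9972 in the FPKM tables, 0.8946 to 0.9237 among DMSO sorted-cell libraries and 0.9471 to 0.9571 among estradiol ones. The DMSO replicate 2 of the sorted cells had counts for 21340 genes and the others for 27617 to 30143. No library was left out of the tests reported as main results.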

Results

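RNA was sequenced from roots of Arabidopsis thaliana seedlings 5 days old, in 30 libraries that form 10 groups of 3. A first set compared root meristems labelled as a mutant of 6 related Dof transcription factors (the pear sextuple mutant) with the wild type Col-0. A second set used lines in which estradiol induces ZAT14-like or ZAT14, both C2H2 zinc finger genes, under the pWOL promoter, which is active in the root vasculature. In that set, root meristems were taken 10 h or 14 h after 5 µM estradiol or after DMSO, the solvent. The third set used protoplasts sorted by fluorescence from a line in which estradiol induces PLT2, a PLETHORA factor of the root meristem, under the NAC086 promoter of developing sieve elements, after 6 h of 10 µM estradiol or DMSO. Total counts in the sorted-cell libraries ran from 31426740 to 44837397. The tables of FPKM values give no totals; from the steps between their low values, depth was estimated at 17.9 to 26.1 M reads for the pear and Col-0 libraries and 18.2 to 26.8 M for the ZAT libraries. The labels do not say that the libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

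The mutant comparison asks which transcripts differ in root meristems of the pear sextuple mutant, the PEAR genes being mobile regulators of growth around the protophloem. Whole meristems were sequenced, so a change within cells and a change in the share of cell types cannot be told apart. The targeted genes themselves moved in both directions. OBP2 was at 0.18 ± 0.113 FPKM in the libraries labelled pear sextuple and at 6.22 ± 0.737 in Col-0 (SD, n = 3 each). PEAR2 was at 0.0802 ± 0.0847 against 2.69 ± 0.211 FPKM, DOF6 at 0.268 ± 0.138 against 3.21 ± 0.637, and PEAR1 at 1.06 ± 0.0739 against 2.41 ± 0.301. TMO6, in contrast, rose from 12.3 ± 1.05 to 78.6 ± 4.25 FPKM and HCA2 from 0.283 ± 0.0845 to 2.18 ± 0.715. All 6 passed the limma test, with adjusted p from 7.46e-07 for TMO6 to 0.000947 for PEAR1. The labels do not describe the alleles, so a higher transcript level of TMO6 or HCA2 does not show whether a functional product was made. The directions reported here for the mutant rest on the label.

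In the TAIR10.1 annotation these genes lie on chromosome 1 from 2353031 to 2356413 (OBP2), chromosome 2 from 15769086 to 15770805 (PEAR1) and chromosome 3 from 16739247 to 16740546 (DOF6). The other members lie on chromosome 5, from 539249 to 541316 (PEAR2), 24240810 to 24242523 (TMO6) and 25256852 to 25258704 (HCA2). ZAT14 lies on chromosome 5 from 880148 to 881347 and ZAT14-like on the same chromosome from 1238820 to 1240517, each annotated with 1 exon. PLT2 lies on chromosome 1 from 18977176 to 18980618, with 9 exons. Values for all of them are counted over the whole gene.

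**Figure D1:**
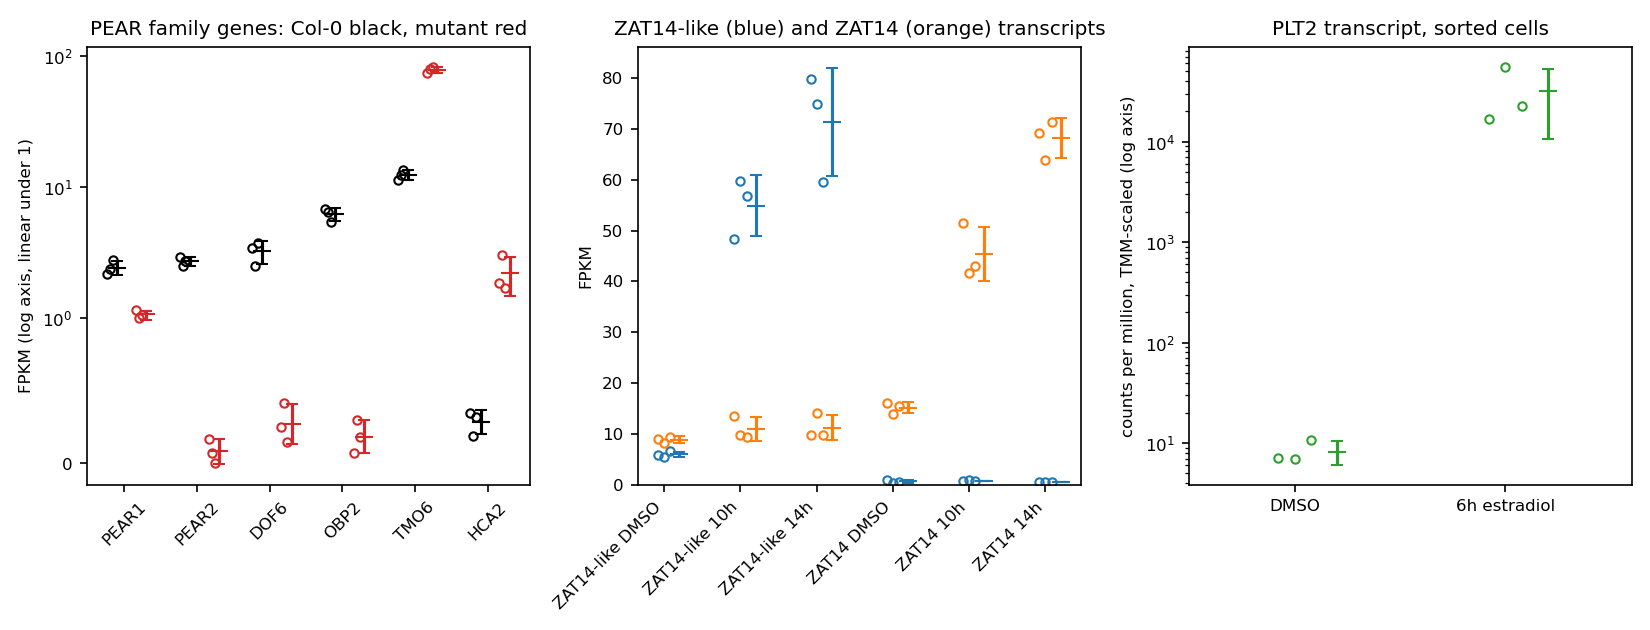
Levels of the targeted genes in every library (circles), with the mean and SD of 3 libraries beside them; the left and right vertical axes are logarithmic (the left is linear under 1 FPKM), the middle is linear. TMO6 and HCA2 were higher in the mutant while the other PEAR genes were lower, each induced ZAT gene was highest in its own line, and PLT2 rose in all 3 estradiol libraries.

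The transcriptome of the mutant differed widely from that of Col-0: of 17062 genes tested, 10778 passed the limma test, 7602 higher and 3176 lower in the mutant. The median of all genes lay 0.21 log2 units above 0 with the FPKM values as deposited. After rescaling each library to the median ratio, 4920 genes were higher and 5076 lower, so changes near that shift have no fixed direction. The largest rises among called genes with a symbol went far beyond it. ICL, the isocitrate lyase of the glyoxylate cycle, was at 415 ± 55.2 FPKM in the mutant and 6.82 ± 4.12 in Col-0, a log2 fold change of 5.90 (adjusted p = 1.02e-05). The metallothionein MT2A was at 1205 ± 164 against 20.9 ± 4.11 FPKM (5.79), AGT3, an alanine:glyoxylate aminotransferase, at 35.2 ± 4.68 against 0.981 ± 0.172 (4.19), and FLC, the floral repressor, at 25.9 ± 3.53 against 0.6 ± 0.218 (4.07). PMT6, EBP, TT10, BT2, bHLH39 and DYL1 completed the 10 largest rises of such genes, with log2 fold changes from 4.02 for PMT6 to 3.43 for DYL1.

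Among genes with a symbol the falls were led by BNQ3, an atypical basic helix-loop-helix protein, at 3.23 ± 0.0573 against 78.9 ± 11.4 FPKM (log2 fold change -4.23, adjusted p = 2.33e-07), and by BZIP9 at 0.212 ± 0.13 against 19.7 ± 4.03 FPKM (-4.08). AGL12, a MADS-box gene of the root, was listed at 0 in all 3 mutant libraries and at a mean of 8.30 ± 3.90 FPKM in Col-0. PDLP7, a plasmodesmata-located protein, fell by 2.99 log2 units, FER1, a ferritin, by 2.88 and SIP2, which belongs to the raffinose metabolism enzymes, by 2.88. LCR68, CYP71B26, ELIP2 and ATGSTF13 made up the rest, with values from -3.70 for LCR68 to -2.94 for ATGSTF13. Each of these 20 genes kept an adjusted p under the threshold in every setting tried, the highest being 0.00123 for LCR68.

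Genes of sieve element maturation were lower where they changed most. Of 14 listed genes, 9 were measured above the filter; 4 fell, 1 rose and 4 did not pass. ENODL9, NAC086, the NAC factor of sieve element enucleation, its target exonuclease NEN4, and APL, a phloem identity factor, fell by 1.73, 1.47, 1.39 and 0.94 log2 units. NAC086 was at 0.0122 ± 0.0212 FPKM in the mutant and 1.81 ± 0.152 in Col-0. The riser, NEN2, had a log2 fold change of 0.38 and lost its call after rescaling. The set test (limma camera, preset correlation) gave adjusted p = 0.0423 for a lower list, 0.074 after rescaling, and adjusted p = 0.476 with an estimated correlation.

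Among upstream regulators of the protophloem and the procambium, several genes rose. Of all 17062 genes tested, 7602 were higher and 3176 lower, and 4920 and 5076 after rescaling. A list count near those shares, here or in the other lists of this comparison, does not set a list apart. Of 12 tested genes of protophloem specification and CLE signalling, 7 rose, 1 fell (CLE25, -0.50) and 4 did not pass; after rescaling these counts were 5 and 2. SMXL5 rose from 1.74 ± 0.157 to 5.84 ± 0.312 FPKM, CVP2 from 3.00 ± 0.654 to 7.58 ± 0.698 and OPS from 5.28 ± 0.282 to 10.48 ± 0.532. Among 13 procambium and HD-ZIP III genes, 11 rose, 1 fell (CNA, -0.26) and 1 did not pass; after rescaling 7 were higher and 1 lower. LOG3, a cytokinin-activating enzyme, PHV and TMO5 rose by log2 fold changes of 1.00, 0.70 and 0.73. Neither list passed camera (adjusted p = 0.562 and 0.0957).

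Several root meristem regulators rose in this comparison, though not as a list by the set test. Of 13 tested genes of the PLETHORA and stem cell niche list, 8 rose and none fell, against 7 and 0 after rescaling. RGF1, a root meristem growth factor peptide, rose from 3.89 ± 0.876 to 25.5 ± 0.786 FPKM, PLT5 from 1.23 ± 0.392 to 10.8 ± 0.54, PLT1 from 22.5 ± 3.47 to 58.5 ± 4.09, and WOX5, a gene of the quiescent centre, from 1.32 ± 0.407 to 7.83 ± 1.09. PLT2 rose from 11.6 ± 1.51 to 20.8 ± 1.57 FPKM (adjusted p = 0.000314). The list test missed the threshold (camera adjusted p = 0.0551, 0.071 after rescaling). Among root cap markers SMB, BRN1 and BRN2, 3 of 4 tested, rose, BRN1 from 30.4 ± 3.31 to 74.2 ± 5.17 FPKM and SMB from 25.1 ± 3.18 to 60.78 ± 5.1. Of 6 endodermis and cortex markers, CASP5, MYB36 and SGN1 rose and 3 did not pass.

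In ribosome biogenesis 7 of 9 genes fell and 0 rose, with FIB2, fibrillarin, at 221 ± 0.88 FPKM in the mutant and 529 ± 47.5 in Col-0, and NOP56 at 204 ± 9.16 against 426 ± 51.7. Its camera adjusted p was 6.98e-05, and adjusted p = 0.535 with an estimated correlation. In DNA replication 6 of 24 genes fell and 2 rose, against 12 and 0 after rescaling; PCNA2 and PCNA1, the replication clamps, fell by 1.05 and 0.75 log2 units (camera adjusted p = 0.0144, and adjusted p = 0.738 with an estimated correlation). Mitosis genes were mixed, with 8 of 28 higher and 4 lower, but 5 and 9 after rescaling (camera adjusted p = 0.562). CYCA2;1 rose by a log2 fold change of 1.80 while CDKB1;2 fell from 19.6 ± 1.32 to 5.75 ± 0.163 FPKM. In cell wall loosening 6 of 12 genes fell, among them EXPA10, XTH5 and XTH17, and EXPA17 and XTH9 rose (camera adjusted p = 0.0114, 0.0546 after rescaling, and adjusted p = 0.476 with an estimated correlation).

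Of 11 clock genes tested 9 rose and 0 fell, 8 and 0 after rescaling, with TOC1 from 21.3 ± 2.75 to 49.7 ± 2.66 FPKM and LUX from 26.7 ± 2.45 to 55.7 ± 3.72. Camera gave adjusted p = 0.0696 for this list and 0.0389 after rescaling, and adjusted p = 0.476 with an estimated correlation and no rescaling. The labels give no clock hour of harvest, so whether both genotypes were harvested at the same hour is not known. Among cytokinin response genes 5 of 10 rose, ARR16 from 0 in all Col-0 libraries to 1.98 ± 0.285 FPKM, and ARR7 fell by 1.00 log2 unit; after rescaling 4 were higher and 3 lower. In the auxin response list IAA19, PIN3 and GH3.1 fell and IAA2 rose, of 13 tested, against 5 lower and 1 higher after rescaling. Cell cycle inhibitors and endocycle genes were split, 7 higher and 3 lower of 19, but 7 and 7 after rescaling. Of 12 xylem genes 5 rose, MC9 and BFN1 most, and 3 did so after rescaling. ROP GTPases and RopGEFs had 6 higher and 2 lower of 12 (4 and 3 after rescaling), root hair and epidermis markers 3 and 1 of 7 (0 and 1 after rescaling), and stress markers 2 (ZAT10, ZAT12) and 1 (JAZ10) of 8 (1 and 1 after rescaling). Companion cell genes were represented by 2 measured members, of which SUC2 rose; after rescaling 1 was higher and 1 lower. The green tissue markers LHCA1 and LHCB1.3 were higher of 3 tested, and neither passed after rescaling. Camera gave no call for these remaining lists, the PEAR family included (adjusted p = 0.0957, 2 higher and 4 lower).

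Adjusted over the list alone, the counts higher and lower were 7 and 3 for mitosis, 1 and 6 for DNA replication, 3 and 0 for root hair and epidermis, 3 and 0 for green tissue, and 1 and 1 for stress, and for the other lists they equalled those above. Leaving out single libraries left between 9270 and 10851 genes called. With an absolute log2 fold change of at least 1 added to the test, 2047 genes passed, 1560 higher and 487 lower.

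**Figure D2:**
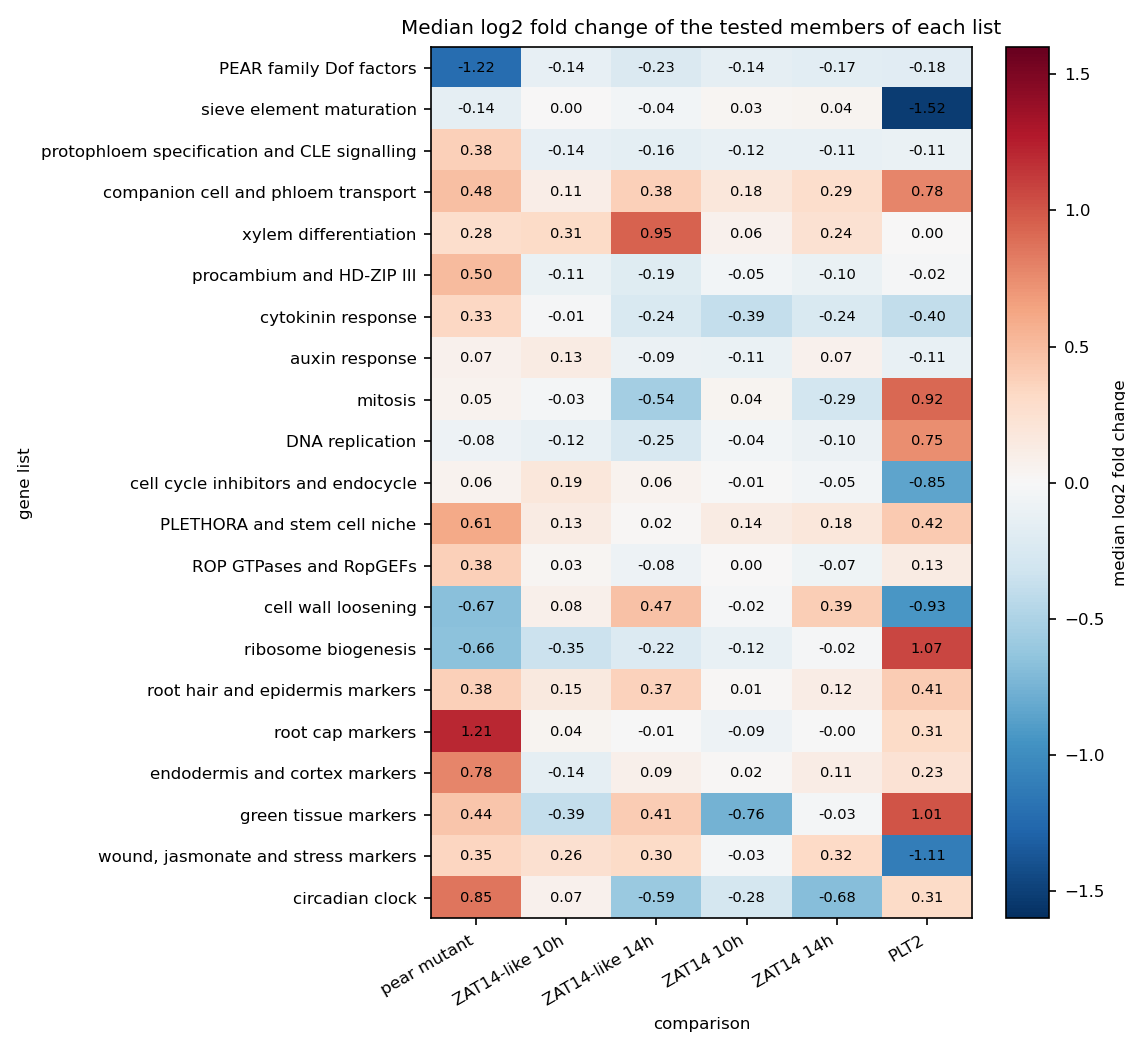
Median log2 fold change of the tested members of each of 21 gene lists (vertical axis) in 6 comparisons (horizontal axis), printed in each cell and coloured from blue (lower) to red (higher). Mutant values are not corrected for the 0.21 shift of all genes; the lowest median is that of sieve element maturation in PLT2-induced cells, -1.52.

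The induction lines ask which genes respond when ZAT14-like or ZAT14 is induced in the vasculature. Each induced gene rose in its own line. ZAT14-like went from 5.98 ± 0.572 FPKM with DMSO to 54.9 ± 5.97 at 10 h and 71.4 ± 10.6 at 14 h in the ZAT14-like line (SD, n = 3). In the ZAT14 line it stayed at 0.677 ± 0.282 with DMSO, 0.766 ± 0.0834 at 10 h and 0.518 ± 0.0313 at 14 h. ZAT14 went from 15.2 ± 1.115 to 45.4 ± 5.39 and 68.2 ± 3.89 FPKM in the ZAT14 line, and was at 8.89 ± 0.647, 10.97 ± 2.28 and 11.25 ± 2.504 in the ZAT14-like line, where its change did not pass (adjusted p = 0.125 over both times). With DMSO alone, 17 genes differed between the lines, 9 higher and 8 lower in the ZAT14-like line, and ZAT14-like was among them (log2 fold change 2.07, adjusted p = 7.45e-08); the count was 10 without the ZAT14-like DMSO replicate 2 or the ZAT14 DMSO replicates 1 or 4, 9 without the 3 libraries numbered 2 and 8 in a fit of the DMSO groups alone. No line without a transgene was given estradiol, so the effect of the inducer itself was not measured.

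After induction of ZAT14-like, 2530 of 17157 genes differed from DMSO over the mean of both times, 1642 higher and 888 lower. Among the largest rises of genes with a symbol, scpl37, a serine carboxypeptidase-like gene, was listed at 0 in the DMSO libraries and reached 6.996 ± 0.381 FPKM at 10 h and 32.9 ± 4.21 at 14 h. WOX5 went from 0.605 ± 0.193 to 23.2 ± 5.48 and 22.9 ± 1.28 (log2 fold change 3.90, adjusted p = 2.66e-10), and WVD2, a microtubule-associated protein, from 0.607 ± 0.0324 to 17.3 ± 5.04 and 20.4 ± 1.51. XCP1, a protease of maturing xylem vessels, went from 3.51 ± 1.51 to 14.8 ± 0.678 and 29.0 ± 4.26. E12A11, PMZ, LEA3, SFH3 and XTH30 rose by log2 fold changes of 3.23, 2.80, 2.65, 2.50 and 2.20.

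The falls in that line were smaller. ACL5, a thermospermine synthase that restrains xylem maturation, dropped from 10.8 ± 0.283 to 4.40 ± 0.69 and 1.82 ± 0.582 FPKM (log2 fold change -1.61, adjusted p = 9.63e-08). TMO5, a basic helix-loop-helix factor of vascular cell division, went from 8.80 ± 0.669 to 3.297 ± 0.645 and 2.401 ± 0.205, and LAX2, an auxin influx carrier, from 20.0 ± 1.59 to 9.61 ± 0.543 and 7.04 ± 0.349. PAL2, CYP82F1, DTX35, PIP2;8, EXLA2, TBL36 and AGO10 also fell, from -1.48 for PAL2 to -0.69 for AGO10. The calls of PAL2 and DTX35 were lost in at least 1 setting, with adjusted p up to 0.164 and 0.283.

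Many xylem genes rose. Of 18 tested, 10 rose, 1 fell (ACL5) and 7 did not pass; adjusted over the list alone, 13 rose and 1 fell. MYB46, a switch of secondary wall formation, went from 0.193 ± 0.168 to 1.45 ± 0.361 and 2.00 ± 0.0958 FPKM, and IRX9, a xylan synthesis gene, from 0.065 ± 0.113 to 0.457 ± 0.132 and 3.34 ± 0.556. Camera gave adjusted p = 1.9e-07, and adjusted p = 0.144 with an estimated correlation. Procambium and HD-ZIP III genes moved down, 6 lower (TMO5, PHB, PHV and CNA the clearest) and 1 higher (PXY) of 14, and 6 lower and 2 higher adjusted over the list alone (camera adjusted p = 0.000504, and adjusted p = 0.144 with an estimated correlation).

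Over both times 12 of 28 mitosis genes fell and 0 rose, 17 and 0 adjusted over the list alone, and 9 of 24 DNA replication genes fell, 12 adjusted over the list alone. Camera gave adjusted p = 6.06e-08 and 2.25e-06 for these lists, and adjusted p = 0.306 with an estimated correlation for both. CDKB2;2, a mitotic kinase, was at 19.5 ± 2.66 FPKM with DMSO, 18.7 ± 0.347 at 10 h and 11.8 ± 1.21 at 14 h. In ribosome biogenesis 8 of 9 genes fell, FIB2 from 359 ± 21.2 to 271 ± 26.6 and 288 ± 29.2 FPKM, and all 9 adjusted over the list alone (camera adjusted p = 2.48e-06, and adjusted p = 0.306 with an estimated correlation). Protophloem specification had 2 genes lower of 12, CVP2 and SMXL5, and the same count adjusted over the list alone (camera adjusted p = 0.0183, and adjusted p = 0.201 with an estimated correlation). The sieve element list had 0 called genes of 11 at either adjustment, with a median log2 fold change of -0.01.

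Other lists held a few called genes each and did not pass camera. In the stem cell niche list WOX5, BBM, JKD and RGF1 rose and SHR fell. Auxin response genes split, GH3.2, GH3.3, IAA2 and IAA19 higher and GH3.5, IAA20, IAA30 and GH3.6 lower of 14, and CKX7, CKX3 and ARR7 rose among 11 cytokinin response genes. KRP7, SMR1 and SMR4, cell cycle inhibitors, rose by log2 fold changes of 0.45, 0.42 and 0.46. AHA3, XTH4, XTH5, WRKY40 and ZAT10 rose, and ROPGEF1, CCA1 and LHY fell, each with a highest adjusted p above the threshold across settings. The PEAR family, root hair, root cap, endodermis and green tissue lists had 0 genes called here.

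The count of 2530 was 1192 and 978 without DMSO replicates 1 and 2 and reached 3133 without the 10 h replicate 4; it fell to 962 when the 3 libraries numbered 2 were left out. A fit of this line alone called 1237 genes, and 177 passed with an absolute log2 fold change of at least 1. With the replicate number as a block 621 were called, although same-numbered libraries were not shown to be paired.

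Induction of ZAT14 moved fewer genes: 563 passed over both times, 389 higher and 174 lower. WVD2 rose from 0.763 ± 0.195 FPKM to 8.998 ± 2.28 at 10 h and 17.7 ± 1.08 at 14 h, WOX5 from 0.693 ± 0.328 to 7.27 ± 2.11 and 10.1 ± 2.38, and XCP1 from 2.93 ± 1.53 to 7.45 ± 1.41 and 15.0 ± 0.892. scpl37, listed at 0 with DMSO, was at 1.499 ± 1.20 and 11.2 ± 1.32. DTA4, PMZ, CP1, SFH3 and ERD14 rose by log2 fold changes of 1.77, 1.67, 1.37, 1.36 and 1.16. ACL5 went from 10.2 ± 0.325 to 6.17 ± 0.908 and 3.499 ± 0.309 FPKM (log2 fold change -0.98, adjusted p = 0.000136). Among the falls, PAL2, an entry enzyme of phenylpropanoid synthesis, CYP82F1, DTX35 and UGT78D2, a flavonoid glucosyltransferase, changed by -1.85, -1.77, -1.75 and -1.52, and MYB32, ABCI21, ANNAT4, ABCI20 and MYB7 by -1.21 to -1.03. Their levels varied between the 10 h libraries, UGT78D2 at 54.7 ± 33.6 FPKM, and each of these falls except those of CYP82F1 and ACL5 lost its call in at least 1 setting.

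By list, 3 stem cell niche genes of 13 rose (WOX5, JKD and BBM), 4 adjusted over the list alone, and camera gave adjusted p = 0.000574, and adjusted p = 0.1 with an estimated correlation. In the cytokinin response list ARR8 fell, while adjusted over the list alone 7 of 11 fell and 1 rose (camera adjusted p = 0.000571, and adjusted p = 0.261 with an estimated correlation). CCA1 and ELF3 fell among 12 clock genes, 6 adjusted over the list alone (camera adjusted p = 0.000145, and adjusted p = 0.261 with an estimated correlation). Xylem genes XCP1 and CESA4 rose and ACL5 fell of 18, while adjusted over the list alone 7 rose and 2 fell (camera adjusted p = 0.205). TMO5 and AHP6 fell in the procambium list, 3 adjusted over the list alone (camera adjusted p = 0.0457, and adjusted p = 0.328 with an estimated correlation). For mitosis, DNA replication and ribosome biogenesis no gene passed at either adjustment, with list medians of -0.11, -0.09 and -0.08; camera gave adjusted p = 0.000418, 0.000884 and 0.0339, and adjusted p = 0.533, 0.533 and 0.607 with an estimated correlation. SMXL5, GH3.5, IAA20, IAA30 and ROPGEF1 fell and GH3.3 rose, and the other lists had no called gene; adjusted over the list alone, 4 auxin response genes rose and 3 fell, 3 stress markers rose and 1 fell, and 1 root hair marker rose. Without DMSO replicates 2 and 4 the count of 563 fell to 330 and 208, it was 244 without the 3 libraries numbered 2, and 55 genes passed with an absolute log2 fold change of at least 1.

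Both lines moved many genes the same way. In all, 343 genes rose and 108 fell in both lines, where independent lists would share 37.2 and 9.01. The 451 genes called the same way in both ZAT lines became 283 without ZAT14 DMSO replicate 2, 197 without ZAT14 DMSO replicate 4 and 193 without the 3 libraries numbered 2. Those 3 had estimated depths of 25.5 to 26.8 M reads, against 18.2 to 23.4 M in the other ZAT libraries. Ribosomal protein genes held 20.5% to 21% of their FPKM sum, against 16.6% to 19.6%. Each DMSO group holds a library numbered 2, but among the estradiol groups only ZAT14 at 10 h does. A difference tied to that number could move both lines alike, so independent lists are not a full baseline. AZG2, a purine permease, and AT5G62998 moved in opposite directions; they are named after their values were seen. Across genes the log2 fold changes of the lines correlated with a Pearson r of 0.709 and a Spearman rho of 0.576, and genes are not independent replicates. Within a line, the 10 h and 14 h changes share DMSO libraries; their r was 0.615 in the ZAT14-like and 0.477 in the ZAT14 line, where unchanged simulated groups gave 0.496. Their covariances, 0.0609 and 0.0284, exceeded the simulated 0.0092.

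**Figure D3:**
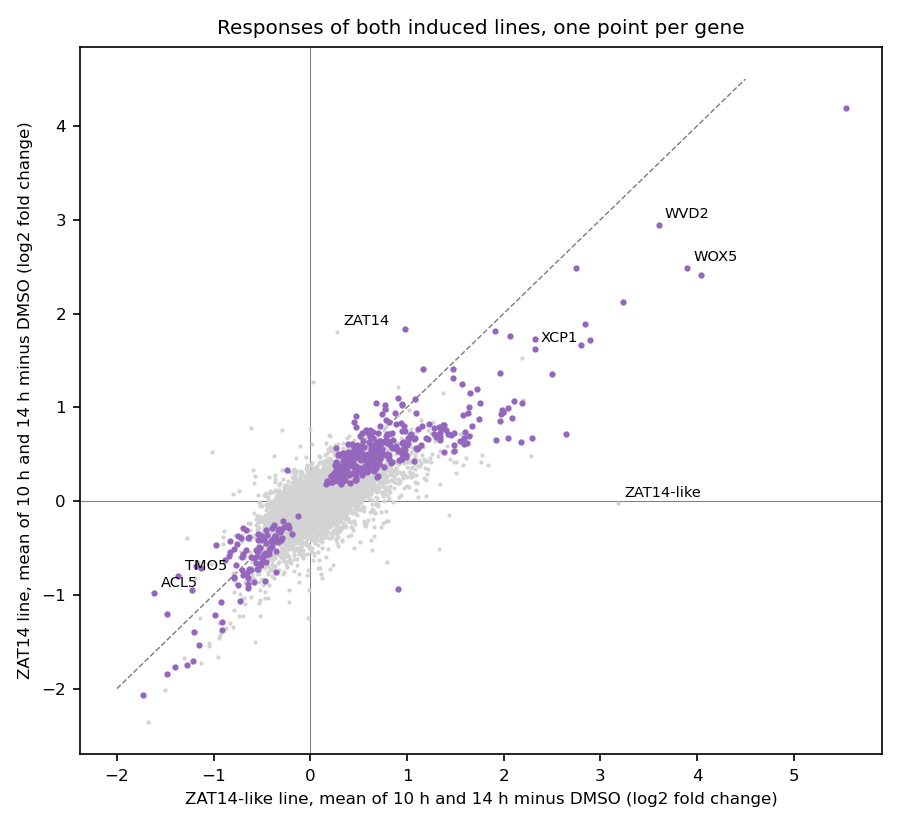
Log2 fold change (log2 FPKM + 1 scale) of 17157 genes after induction in the ZAT14-like line (horizontal axis) and the ZAT14 line (vertical axis), with genes that passed in both lines in purple and equal change on the dashed line. WOX5, WVD2 and XCP1 rose and ACL5 and TMO5 fell in both, while each induced gene changed in its own line.

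The difference between the responses was tested directly. It passed for 62 genes, 56 with a more positive response in the ZAT14-like line and 6 with a more negative one (1295 at an unadjusted p under the threshold). Besides the induced genes, LEA3, scpl37, CPK16, a calcium-dependent protein kinase, and WOX5 responded more in the ZAT14-like line, by 1.93, 1.63, 1.62 and 1.41 log2 units. AZG2, LAX2 and PHB had differences of -0.57, -0.49 and -0.40. Xylem genes as a list leaned to the ZAT14-like line, with a median difference of 0.50. None of 18 passed over all genes, 8 higher and 1 lower did so adjusted over the list alone, and camera gave adjusted p = 2.19e-10, and adjusted p = 0.0532 with an estimated correlation. The count of 62 was 25 with a pseudocount of 0.1, 106 without a filter on low values, 29 without the 3 libraries numbered 2, and 39 and 38 without the ZAT14-like DMSO replicates 1 and 2. It was 5 with the replicate number as a block, although same-numbered libraries were not shown to be paired.

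Time after induction separated the libraries of each line further. At 10 h 2365 genes (1537 higher, 828 lower) and at 14 h 2123 genes (1353 and 770) differed from DMSO in the ZAT14-like line, against 551 (336 and 215) and 735 (489 and 246) in the ZAT14 line. Between 14 h and 10 h, 1485 genes differed in the ZAT14-like line, 639 higher and 846 lower, and 863 in the ZAT14 line, 412 higher and 451 lower. After median-ratio rescaling 740 were higher and 714 lower in the ZAT14-like line, and 431 and 429 in the ZAT14 line. Fits of the compared groups alone called 429 genes at 10 h and 290 between times in the ZAT14-like line, and 52 at 10 h and 1113 at 14 h in the ZAT14 line. Without single libraries the ZAT14-like counts ran from 1077 (DMSO replicate 2) to 3726 (10 h replicate 4) at 10 h, down to 1112 (DMSO replicate 2) at 14 h and from 716 (14 h replicate 3) to 2413 (10 h replicate 4) between times. The ZAT14 counts went down to 150 (DMSO replicate 4), 350 (DMSO replicate 2) and 421 (14 h replicate 3). Without the 3 libraries numbered 2, the counts against DMSO were 1049 and 1060 in the ZAT14-like line and 359 and 310 in the ZAT14 line. Mitosis genes fell with time in both: 21 of 28 in the ZAT14-like line and 12 in the ZAT14 line (24 and 21 adjusted over the list alone). CDKB2;2 fell by 0.62 and 0.50 log2 units and CYCB2;3 by 0.68 and 0.51. Camera gave adjusted p = 3.29e-17 and 1.26e-13, and adjusted p = 0.262 and 0.234 with an estimated correlation. Against DMSO, 22 of 28 mitosis genes were lower at 14 h in the ZAT14-like line and 2 (CYCB2;3 and PLE) in the ZAT14 line, and none at 10 h in either. Adjusted over the list alone, 26 were lower at 14 h in the ZAT14-like line, 16 lower and 1 higher in the ZAT14 line, and none passed at 10 h.

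Many xylem genes rose with time. In the ZAT14-like line 10 of 18 were higher and 3 lower (ACL5, VND1 and VND2), and in the ZAT14 line 4 were higher and 1 lower (ACL5); adjusted over the list alone these counts were 10 and 5, and 8 and 1. Camera gave adjusted p = 0.000779 and 0.00592, and adjusted p = 0.262 and 0.247 with an estimated correlation, with XCP1 higher by log2 fold changes of 0.91 and 0.93 and LAC4, a laccase of lignification, by 1.84 and 0.64. Clock genes changed beside these groups: 7 of 12 fell and 1 rose (PRR7) in each line, CCA1 by 1.36 and 1.04 log2 units and RVE1 by 2.12 and 2.16. For the clock list camera gave adjusted p = 1.83e-05 and 3.43e-05, and adjusted p = 0.262 and 0.234 with an estimated correlation. The labels give the time since induction and no clock hour of harvest. Leaving out the 14 h replicate 3 lowered the counts of 1485 and 863 genes to 716 and 421, and leaving out the 10 h replicate 4 of the ZAT14-like line raised the former to 2413.

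**Figure D4:**
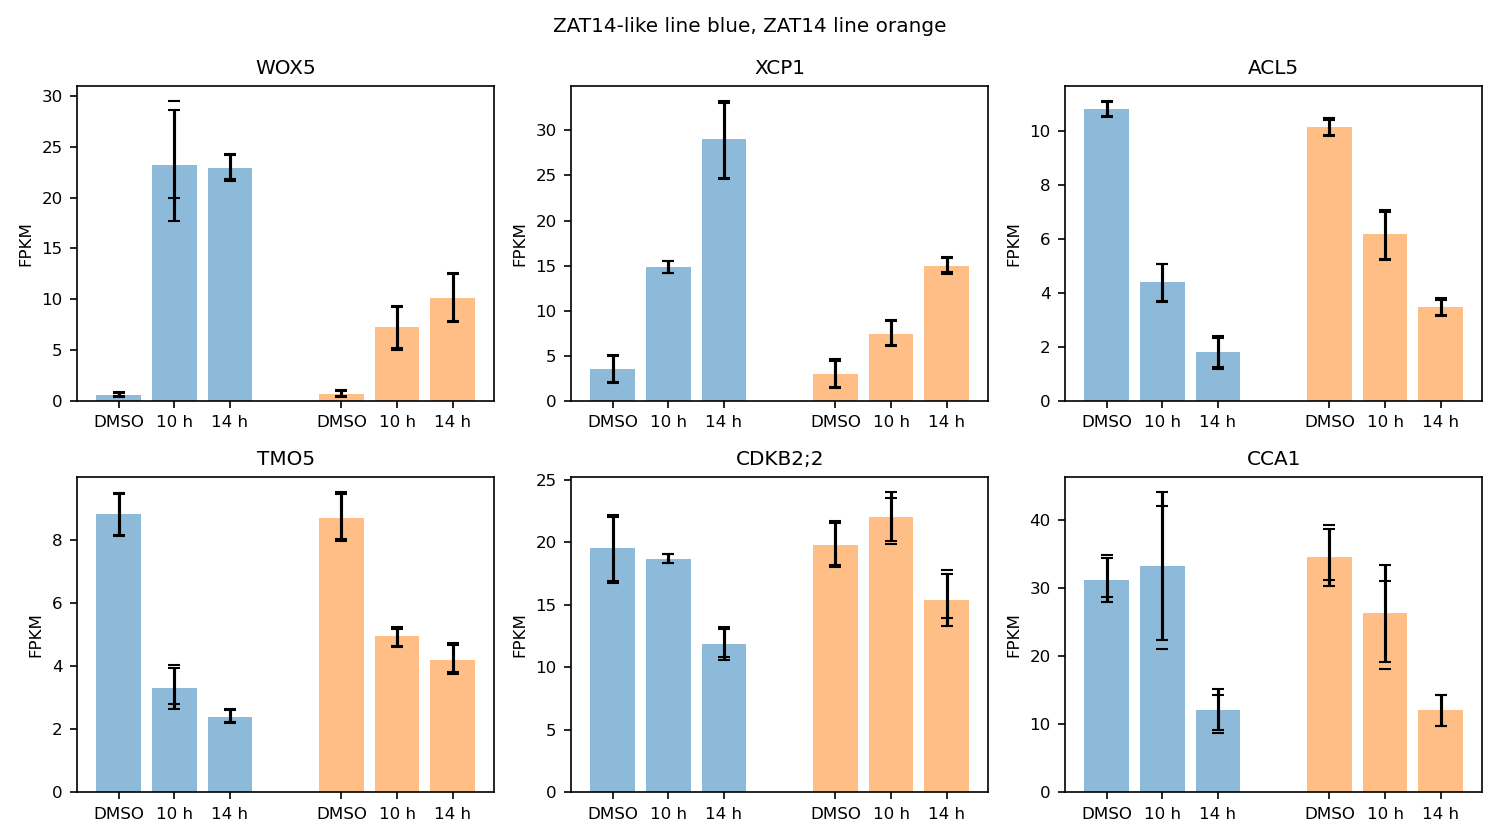
Mean FPKM (bars) of 6 genes with DMSO and at 10 h and 14 h after estradiol in the ZAT14-like line (blue) and the ZAT14 line (orange), with the SD of 3 libraries as error bars and short ticks at the lowest and highest library. WOX5 and XCP1 rose, ACL5 and TMO5 fell, and CDKB2;2 and CCA1 were lowest at 14 h in both lines.

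The PLT2 comparison asks how developing sieve element cells respond when PLT2 is kept on. PLT2 itself went from 8.22 ± 2.18 to 31580 ± 20900 CPM (TMM-scaled counts relative to library size; SD, n = 3), a log2 fold change of 11.91, and made up 2.01%, 7.07% and 2.59% of the counts in the estradiol libraries. Control cells had been sorted for the red reporter alone and estradiol-treated cells for red and yellow fluorescence, so sort gate and induction differ together. Of 24673 genes tested with edgeR, 162 passed, 64 higher and 98 lower, and 5139 had an unadjusted p under the threshold. These calls were fragile. They numbered 1900 without DMSO replicate 1, 0 without DMSO replicate 2 (4489 at an unadjusted p) and 1 without DMSO replicate 4, and 4, 3 and 7 without estradiol replicates 1, 2 and 3. DESeq2 called 3070 genes, limma-voom with sample weights 17, and edgeR 92 with DESeq2 size factors and 626 without a filter. No gene named for this comparison kept its call in every setting, PLT2 included (adjusted p = 0.0166, up to 0.44).

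With that limit, the largest rises after PLT2 among genes with a symbol included EXL3, COBL1 and XTH9, a wall-modifying enzyme. EXL3, related to EXORDIUM, went from 4.499 ± 1.02 to 114.5 ± 23.5 CPM (log2 fold change 4.66, adjusted p = 0.00621) and COBL1 from 2.85 ± 0.497 to 69.7 ± 29.1 (4.61). The kinesin KICP-02 went from 13.3 ± 3.71 to 156 ± 26.4, and MLS, NUC-L2, ENODL2, ROP9 and EXL5 had log2 fold changes from 5.99 to 3.31. Falls included ZAT14-like, from 76.4 ± 35.2 to 5.46 ± 2.82 CPM (-3.81, adjusted p = 0.0436), and PP2-A9, a phloem protein, from 139 ± 69.6 to 9.64 ± 5.59. MES9, ESM1, GLP7, SRO3, SRO2, NPC4, NAC011 and WRKY45 fell by 5.29 to 3.13 log2 units. ZAT14 was at 415 ± 163 CPM after estradiol and 1249 ± 532 with DMSO, which did not pass (adjusted p = 0.115).

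Sieve element maturation genes lay lower after PLT2 induction as a list. Among 14 genes the median log2 fold change was -1.52; 1 passed over all genes, SEOR1, a filament protein of sieve elements, from 534 ± 190 to 78.0 ± 35.1 CPM, and 10 were lower adjusted over the list alone. NAC045 and NAC086 had values of -2.17 and -1.49 and did not pass. Camera gave adjusted p = 1.44e-08, and adjusted p = 0.633 with an estimated correlation. Without single libraries the list median ran from -1.76 to -1.23. DNA replication genes leaned higher, with MCM5 called of 24, 7 adjusted over the list alone and a median of 0.75 (camera adjusted p = 8.61e-05, and adjusted p = 0.667 with an estimated correlation). Mitosis genes had a median of 0.92, no call of 28 over all genes and 1 adjusted over the list alone (camera adjusted p = 0.00837, and adjusted p = 0.633 with an estimated correlation).

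Ribosome biogenesis (median 1.07, 0 of 9 called at either adjustment) and cell cycle inhibitors and endocycle (median -0.85, 0 of 20 called, 6 lower and 1 higher adjusted over the list alone) each had a camera adjusted p = 0.00408, and adjusted p = 0.667 and 0.441 with an estimated correlation. The PLETHORA and stem cell niche list, which holds the induced gene, gave camera adjusted p = 0.00837, and adjusted p = 0.667 with an estimated correlation; PLT7 had a log2 fold change of 5.58 and did not pass. Stress markers lay lower as a list with 0 of 14 called at either adjustment (camera adjusted p = 0.0377, and adjusted p = 0.633 with an estimated correlation). Companion cell genes had a median of 0.78 with 0 of 12 called, 1 lower adjusted over the list alone. In other lists XCP2 and EXPA1 fell and ROP9 and XTH9 rose, and no further gene passed; adjusted over the list alone, 4 protophloem genes were higher and 2 lower. Across 16510 genes, the PLT2 changes correlated with those of ZAT14-like induction with a Pearson r of -0.287 and a Spearman rho of -0.408 and with those of ZAT14 induction at -0.112 and -0.190, and across 16781 genes with those of the mutant at -0.0522 and -0.101, genes not being independent replicates.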

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

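Apart from the splits of the samples and the test without the DMSO library with the fewest detected genes, the tests of explanations in this part were chosen only after the results were seen.

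The responses of the ZAT14-like and ZAT14 lines differed by a direct test for 62 genes. The differences, ZAT14-like line minus ZAT14 line in log2 units, were 3.204 for ZAT14-like, 1.93 for LEA3, 1.63 for scpl37, 1.62 for CPK16, 1.41 for WOX5, 1.20 for GH3.2, 1.14 for SFH3, 1.112 for E12A11 and 0.95 for ARR7, and -1.53 for ZAT14, -0.57 for AZG2, -0.49 for LAX2 and -0.40 for PHB. Lists differed too at the preset correlation (camera adjusted p): xylem differentiation 2.19e-10, ribosome biogenesis 8.66e-05, mitosis 0.000251, cytokinin response 0.00056, and procambium and DNA replication 0.00348 each. None of these passed with an estimated correlation, with adjusted p = 0.0532 for xylem, 0.215 for cytokinin response and procambium, 0.547 for ribosome biogenesis and 0.574 for mitosis and DNA replication. Of 100 splits drawn, 1 (the real one) gave as many as 62 genes, the highest other giving 0, which argues against chance.

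Time points differed within the ZAT14-like line for 1485 genes. From 10 h to 14 h, scpl37 changed by 2.08 log2 units, IRX9 by 1.57, E12A11 by 1.3, XCP1 by 0.91, GH3.2 by 0.78, SFH3 by 0.59, AHA3 by 0.58, XTH5 by 0.47 and GH3.3 by 0.46. Lower at 14 h were CCA1 (-1.36), ACL5 (-0.95), PIP2;8 (-0.85), CDKB2;2 (-0.62), ARR7 (-0.58), PHB (-0.47), CNA (-0.45), CDKB2;1 (-0.44), LAX2 (-0.40) and KNOLLE (-0.39). The lists that passed camera were mitosis (adjusted p = 3.29e-17), circadian clock (1.83e-05), xylem differentiation (0.000779), DNA replication (0.00495), cell wall loosening (0.0111), cytokinin response (0.0203) and green tissue (0.0369). None passed with an estimated correlation, with adjusted p = 0.475 for DNA replication and adjusted p = 0.262 for each of the others.

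In the ZAT14 line the time points differed for 863 genes. scpl37 changed by 2.38 log2 units, PMZ by 1.08, XCP1 by 0.93, WVD2 by 0.92, CP1 by 0.88, GH3.3 by 0.83, AHP6 by 0.76, SFH3 by 0.67 and ZAT14 by 0.58, and CCA1 by -1.04, ACL5 by -0.67 and ELF3 by -0.42. Lists past the threshold were mitosis (camera adjusted p = 1.26e-13), circadian clock (3.43e-05), auxin response (0.000971), xylem differentiation (0.00592), cell wall loosening and stress markers (0.00693 each), green tissue (0.0325) and DNA replication (0.0411). None passed with an estimated correlation, with adjusted p = 0.0722 for auxin response, 0.234 for mitosis, clock and stress markers, 0.247 for xylem, wall loosening and green tissue, and 0.546 for DNA replication.

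Comparisons of 3 libraries against 3 allow 10 splits, too few for a share under 0.05. In each such comparison 1 split, the real one, gave as many genes: 10778 for the mutant, 2365 and 2123 for ZAT14-like at 10 h and 14 h, 551 and 735 for ZAT14, 1485 and 863 between times, 17 between the lines with DMSO and 162 for PLT2. The highest other was 56 for ZAT14 at 10 h and 0 for the rest. For induction over both times, 1 of 84 splits gave as many as 2530 genes in the ZAT14-like line (highest other 1797). In the ZAT14 line 3 of 84 gave as many as 563 (highest other 984). Both shares lie under 0.05, but these splits exchange 10 h, 14 h and DMSO libraries although the times differ. Mixed groups have a wider spread, and the median of the other splits was 0 genes in each line. The shares therefore do not decide on chance for the induction. The highest splits of the ZAT14 line set the 14 h libraries apart, so time structures these samples.

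More genes rose than fell in the libraries labelled pear sextuple, 70.5% of the called genes. After median-ratio rescaling the share was 49.2%, but that rescaling centres the genes, so a near-even split follows from it and decides nothing; library scaling stays open. The most abundant genes (a fixed number per library) held at least 48.7% of the FPKM sum in each Col-0 library and at most 43.4% in each mutant library, which is consistent with abundant genes lowering the other genes' FPKM in Col-0. A difference in depth is argued against: the mutant to Col-0 ratio of mean estimated depths was 0.946, and the depths of the groups' libraries overlapped. In the DMSO libraries of the ZAT lines, from a separate table, the most abundant genes held 42.4% to 44.3%, nearer the mutant than Col-0. The genotype remains an untested biological explanation of the differing share, and whether the mutant or the Col-0 libraries stand apart is not settled.

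Sieve element maturation genes lay lower in PLT2-induced cells, with a median of -1.52. Most of these genes did not pass over all genes, and the list lost its camera call with an estimated correlation. PLT2 transcripts taking counts from other genes could lower all genes by no more than -0.106 log2 units. The median was taken after TMM scaling, which already acts on a uniform loss, so the comparison with that limit decides little. TMM factors of 0.717 to 1.01 in DMSO and 1.15 to 1.28 in estradiol libraries themselves lower estradiol values relative to DMSO. The limit therefore does not bound the effect of scaling. Without DMSO replicate 2, the library with the fewest detected genes, the median was -1.43, which argues against that library as the cause. The sort gate cannot be told apart from PLT2, since 0 gates were used under both treatments. A response to PLT2 stays open beside it.

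The ZAT14-like and ZAT14 lines shared 451 responding genes. Both DMSO groups hold a library numbered 2, and among the estradiol groups only ZAT14 at 10 h does. A difference tied to that number therefore stays open as a part of the shared response. Estradiol itself as the whole cause cannot be told apart from the 2 related factors. The median ratio of the responses was 1.16 (1.07 to 1.34 without single DMSO libraries, the only ones left out for it), and no line without a transgene was treated. For 32 shared genes the response also passed the difference test, larger in the ZAT14-like line in all 32, and this cannot tell, since the genes were picked by that test and a stronger inducer response in that line would give the same. Time of day at harvest stays open. The clock list differed between 14 h and 10 h in both lines (the larger camera adjusted p was 3.43e-05, and neither passed with an estimated correlation). That contrast leaves out DMSO, so it cannot decide on the shared response against DMSO. Against DMSO over both times, the clock list passed camera at the preset correlation in the ZAT14 line and not in the ZAT14-like line. The hour at which DMSO libraries were taken is not given.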

How the results depend on the processing

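The fits without the 3 libraries numbered 2, the block across both lines and limma-voom were chosen only after the results were seen. Where a count changed, the cause was not tested, except that a fold threshold can by construction not raise a count.

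Among results that answer a comparison, 149 values kept their direction and side of the threshold or stayed within 1.5 times the count, 72 became weaker, 8 stronger and 4 moved; among named genes and lists these were 4059 kept, 603 weaker, 30 stronger and 1 reversed. The reversal was ZAT14-like in the ZAT14 line, -0.02 with all libraries and from -0.11 (without ZAT14 DMSO replicate 2) to 0.11 (without ZAT14 DMSO replicate 1), none passing.

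With an absolute log2 fold change of at least 1, 2047 genes passed for the mutant, 179, 263 and 177 for ZAT14-like at 10 h, 14 h and over both, 91, 100 and 55 for ZAT14, 151 and 113 between times in the ZAT14-like and ZAT14 lines, 29 for the line difference in response and 10 between lines with DMSO. With the replicate number as a block the ZAT14-like counts were 603, 736 and 621, and those of ZAT14 188, 336 and 292. There were 361 between times in the ZAT14 line, 5 for the difference in response, 7 with DMSO, 1829 for PLT2 and 201 shared genes. Deviations of same-numbered libraries from their group means correlated at -0.161 to 0.417 in the ZAT table (13 pairs). Their median there was -0.0043, against -0.0258 for other pairs within a line, and pairs across the lines were not compared. The sorted cells gave -0.0475 and 0.17, with a median of 0.0455 for other pairs. Pairing was thus not shown in these sets. In the mutant table the same-numbered pairs, at 0.253 and 0.355, lay above all 7 others (median -0.0506, highest 0.16). Pairing stays open there, and the block left 9946 genes called. A block across both lines gave 1623 for ZAT14-like induction. Fits of the compared groups only gave 429 for ZAT14-like at 10 h and 1237 over both times, 52 and 1113 for ZAT14 at 10 h and 14 h, 290 between times in the ZAT14-like line and 8 with DMSO. Without the 3 libraries numbered 2 there were 1049, 1060 and 962 for ZAT14-like, 359, 310 and 244 for ZAT14, 29 for the difference in response, 9 with DMSO and 193 shared genes. The difference in response gave 25 with a pseudocount of 0.1 and 106 without a filter. PLT2 gave 3070 with DESeq2, 92 with DESeq2 size factors (48 higher, 44 lower), 626 without a filter and 17 with limma-voom.

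Leaving out single libraries gave 9270 to 10851 genes for the mutant. For ZAT14-like it gave 1077 (without DMSO replicate 2) to 3726 (without 10 h replicate 4) at 10 h, 1112 (DMSO replicate 2) to 2065 at 14 h, and 978 (DMSO replicate 2) to 3133 over both. For ZAT14 the ranges were 150 (DMSO replicate 4) to 520, 350 (DMSO replicate 2) to 748, and 208 (DMSO replicate 4) to 626. Between times they were 716 (14 h replicate 3) to 2413 (10 h replicate 4) in the ZAT14-like and 421 (14 h replicate 3) to 865 in the ZAT14 line. The difference in response gave 38 to 68, lines with DMSO 10 to 16 (both lowest without ZAT14-like DMSO replicate 2), genes called the same way in both ZAT lines 197 (ZAT14 DMSO replicate 4) to 467, and PLT2 0 (DMSO replicate 2; edgeR, 4489 at an unadjusted p) to 1900 (DMSO replicate 1).

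Depth limits low genes: the FPKM depths are estimates, and in the sorted cells DMSO replicate 2 had counts for 21340 genes.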

Other observations

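Among the tests of this part, the neighbour test was chosen only after the result was seen; the scaling test of ribosomal proteins was written before it. The 4 gene groups below were formed after values had been seen, and a first version of the carbon group held only genes that rose and was not used.

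Ribosomal protein genes lay lower in the libraries labelled pear sextuple: of 297 tested, 30 were higher and 211 lower (median -0.46), and 12 and 240 after rescaling (median -0.69). After rescaling 88.9% were negative. Rescaling lowers every gene in the mutant relative to Col-0, so this share could only rise and the test cannot decide on library scaling. With either scaling the median of these genes lay below that of all genes (0.21 as deposited, 0.00251 rescaled). They held 18.7% to 19.8% of the FPKM sum in mutant and 25.2% to 27.1% in Col-0 libraries. The DMSO libraries of the ZAT lines, from a separate table, held 18.8% to 21%, nearer the mutant than Col-0. Whether the mutant or the Col-0 libraries stand apart is therefore not settled. Of 296 tested in the ZAT lines, 5 were higher and 8 lower for ZAT14-like at 10 h, 5 and 18 at 14 h, 3 and 0 for ZAT14 at 10 h and 1 and 2 at 14 h. In the PLT2 cells none of 316 passed edgeR (median 0.51).

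Iron genes in the mutant were 6 higher and 3 lower of 11 (5 and 3 rescaled): bHLH39 3.49, OPT3 1.68, BHLH101 1.35, FRU 1.23, FRO2 1.13 and BTS 0.35, against FER1 -2.88, FER3 -1.84 and FER4 -1.40. At most 1 of 10 passed in any ZAT comparison. Carbon genes were 5 higher of 6 in the mutant (ICL, BT2, DYL1, MLS, ASN1). Of 6 in the ZAT table, 4 were higher for ZAT14-like at 10 h, 3 higher and 1 lower at 14 h, 3 higher for ZAT14 at 10 h and none called at 14 h; for PLT2 MLS alone rose of 8. Flavonoid genes were 1 higher (MYB32) and 7 lower of 12 in the mutant (1 and 9 rescaled), and at 10 h 8 of 13 were lower for ZAT14-like and 11 for ZAT14, against 1 each at 14 h; the difference between the lines passed for none. In PLT2 cells no iron or flavonoid gene passed edgeR.

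Some genes were near 0 FPKM in one genotype and at 5 FPKM or more in the other. Chromosome segments of another strain in the mutant might place such genes side by side. Only genes directly next to each other among those above the filter counted as a pair, so close genes that were not adjacent were missed. AT3G60960, AT3G60980 and AT3G61010, close by locus code and named after their values were seen, were near 0 in the mutant and at 7.84, 9.2 and 12.5 FPKM in Col-0. Of 44 genes 1 neighbouring pair was seen, where shuffles gave a mean of 0.115 (permutation p = 0.109 over 10000 shuffles), too few to decide; an earlier definition with 288 genes gave 8 pairs against 4.86 (permutation p = 0.114).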
